A study of Mus musculus with 12 samples.

How the data were processed

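Whole-transcriptome RNA sequencing was carried out on mouse brain tissue from 4 groups with 3 libraries each. Per the labels, treated mice received 5-aminolevulinic acid (5-ALA) at 20 mg/kg, and after 30 min they were exposed to 635 nm laser light at a fluence of 20 J per square centimetre. This is photodynamic therapy (PDT): 5-ALA is a precursor of heme that cells turn into protoporphyrin IX, a pigment that light activates. Tissue was taken 1.5 h, 12 h or 48 h later. Control libraries are titled PBS and labelled untreated, and the labels do not say whether control mice had light or an injection. The mice were perfused with 0.9% NaCl, and RNA was extracted with Trizol and a total RNA kit. The labels name both BALB/c and C57BL/6 as the strain, and they give neither the brain region nor the time of day of collection. Whether polyadenylated RNA was selected or ribosomal RNA removed is not stated.

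A single deposited table held 54532 genes with 12 columns of FPKM values, which are fragments scaled by gene length and library depth and were made by the authors. Gene length in bases and coordinates, per the file headers, stood beside them. The submitters' notes name Bowtie 0.12.2 and the mouse build mm8. The counting tool, strandedness and annotation are not given in the notes. Of 54495 gene identifiers shared with GENCODE release M21 on build GRCm38, 98.33% had the same start and end, so positions are given as GRCm38. In each column, FPKM times gene length was a whole multiple of a fixed step for 100% of values, within 0.05 of a step. Dividing by that step gave 15348579 to 17444654 recovered reads per library, listed with the groups in the report. The scaling total behind the deposited FPKM values was not the library's own total. It equalled a median-of-ratios size factor over 18170 genes times the geometric mean of the totals. The deposited FPKM values therefore already carried a between-library normalization by the authors, and no further scaling was applied.

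Of the columns, 11 carried a group and a replicate number found in the sample titles. The remaining column, of the 12 h group, carried a number that no title of that group has, and 1 title of that group had no column. The column was assigned to its group without a replicate number and is called the unnumbered 12 h library. Pearson correlations of the 12 pairs of libraries within groups, across genes on the log2 scale, ran from 0.919 to 0.987. Per gene, pairs differed by 8.7 to 271.7 times the variance of counting noise among genes with at least 20 reads in the pair, so no library was a copy of another. Differences from the group mean were also compared between groups for the 11 pairs of libraries with the same number. Their correlations across genes had a median of -0.004 and a range of -0.264 to 0.156, so the numbers were not treated as pairs.

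Genes above 0.5 FPKM in at least 3 of 12 libraries were tested, 17664 in all. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with the mean-variance trend and 1 fit of all 12 libraries in 4 groups. The fit had 8 residual degrees of freedom and 3.09 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg, and genes below a false discovery rate (FDR) of 0.05 are said to have risen, fallen or changed. The 6 pairwise contrasts and the overall test of 4 groups were computed. All log2 changes come from this fit, with the standard error (SE) of the fit, and fold changes on the log2(FPKM + 1) scale understate those of genes with low values. The p-values measure the spread between libraries, since the labels do not say that each library came from a separate animal.

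From 47 gene lists written down beforehand, 44 had at least 5 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 44 lists in each contrast. Camera with an estimated correlation and limma's fry were run beside it. Fry asks whether the members of a list move, on balance, in the same direction, without comparing them with other genes. Counts of changed members are given over all genes tested and adjusted over the list alone. With the estimated correlation, 2 list calls held among all contrasts: the NF-kB list and the p53 list at 12 h.

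The named genes follow a rule. For each time against control, these were the 8 largest rises and 8 largest falls past the threshold with a mean of at least 1 FPKM and no overlap between the groups. From every list past the threshold came the 2 rising and 2 falling members with the smallest p. To these were added 12 fixed genes: Hmox1, Alas1, Fech, Cldn5, Ocln, Tjp1, Plvap, Aqp4, Gfap, Aif1, Fos and Hspa1a. Between times, the 5 largest rises and falls were taken. Some genes that the rule names are not reported here. Members of a list outside the rule are named where all changed members are listed or as examples, and such examples were chosen after their values were seen. The groups, contrasts, gene lists, rule, tests of the comparisons and other settings tried were fixed before the data were examined, except 3 settings and the tests of patterns that the closing section names as chosen later.

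A gene length trend was measured in each library over 9985 genes with a mean of at least 3 FPKM, as the slope of the log2 difference from the mean of all libraries per doubling of length. Alternatives were quantile normalization, limma without the trend, no filter and a filter at 1 FPKM, a pseudocount of 0.1, only the 2 groups compared, the replicate number as a block, a fold change of at least 2, and each library left out in turn. A further 3 were chosen after the data were seen: values corrected for the length trend by a lowess curve (span 0.3), limma-voom on the recovered reads, and a fit without 1.5 h replicates 1 and 3. A lone library left in a group was assumed to vary like the other groups.

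The pipeline was tested on simulated data made from the mean level of each gene, log-normal noise sized to its fitted spread and Poisson counting noise, with 200 genes raised or lowered per contrast. Of genes changed 2-fold in the reads, 26.9%, 38.8% and 32.8% were called at 1.5 h, 12 h and 48 h, and of those changed 4-fold 75.8%, 81.8% and 87.9%. False calls made up 7.9%, 7.7% and 9.4% of 76, 91 and 96 genes called. A list of 20 genes raised 2-fold was called in all 3 contrasts, with 0 of 43 unchanged lists called in any. The noise was drawn for each gene on its own, so the simulated lists lacked correlation between genes. This 0 therefore does not show how often unchanged lists would be called in the real libraries. A length slope of -0.3 put into 1 library was measured as -0.296 and after correction as 0.002. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.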

Results

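RNA from mouse brain was sequenced in 12 libraries, 3 from untreated controls and 3 from each of 1.5 h, 12 h and 48 h after 5-ALA photodynamic therapy. The series addresses how the transcriptome of mouse brain differs at these times after the treatment. Reads recovered for genes came to 16642402, 17103868 and 16306254 in control replicates 1, 2 and 4 and to 15709617, 16594959 and 15348579 in 1.5 h replicates 1, 2 and 3. The 12 h libraries had 15746042, 16490476 and 15990093 in replicates 1 and 2 and the unnumbered library. Replicates 1, 3 and 4 of the 48 h group had 16247614, 17294975 and 17444654. Values are deposited FPKM as mean ± SD of 3 libraries, log2 changes are given with the SE of the limma fit, and positions are on GRCm38. By the rule that chose them, all genes named among the largest changes had its 3 libraries of a group all above or all below the 3 of the other group.

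A pair of 1.5 h libraries stood apart in RNA composition. Replicates 1 and 3 of the 1.5 h group had higher levels of short genes and lower levels of long genes, with slopes of -0.311 and -0.193 in log2 per doubling of gene length, against 0.077 to 0.104 in controls and 0.098 in 1.5 h replicate 2. Mitochondrial transcripts took 12.43% and 9.14% of their reads, against 4.16% to 6.02% in controls and 4.16% in replicate 2. The mitochondrial ribosomal RNAs took 5.51% and 2.18%, against 0.616% to 0.823% in controls. Slopes were 0.045 to 0.085 at 12 h and -0.054 to 0.015 at 48 h. Correcting each library for this trend put the median log2 change of all genes at -0.12 for 1.5 h against control, 0.15 for 12 h against 1.5 h and 0.13 for 48 h against 1.5 h, from 0.02, 0 and -0.02 before.

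**Figure D1:**
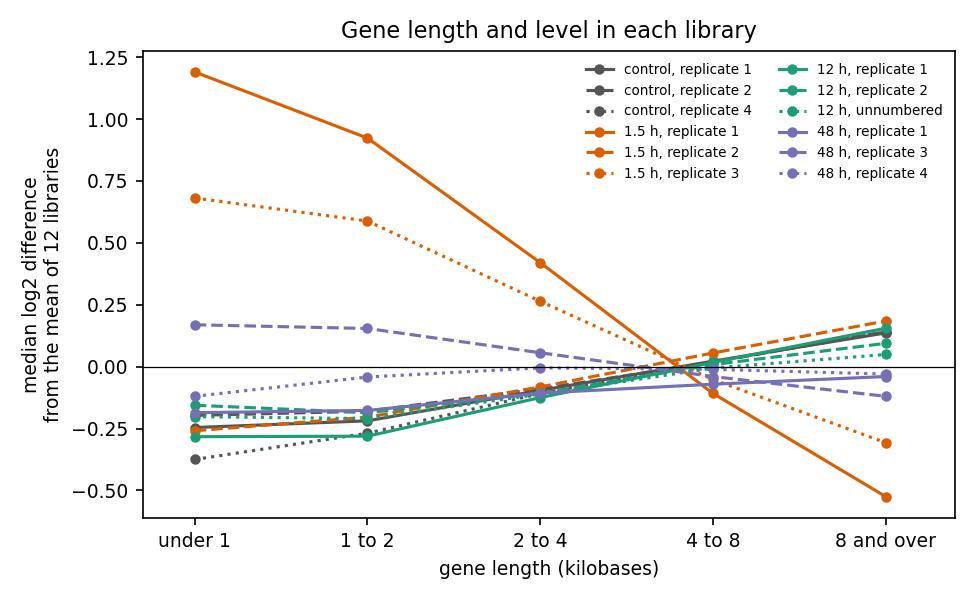
Median log2 difference of each library from the mean of all 12 libraries (vertical axis) for genes in 5 classes of length in kilobases (horizontal axis), with 1 line per library and colours for the 4 groups. In 1.5 h replicates 1 and 3, genes under 1 kilobase lay at 1.19 and 0.68, and those of 8 kilobases and over at -0.53 and -0.31.

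The comparison of 1.5 h with control asks which genes differed soonest after treatment. Hspa1a and Hspa1b, which encode inducible HSP70 chaperones, rose from 2.13 ± 0.722 to 128 ± 39.2 FPKM and from 3.10 ± 0.755 to 179 ± 61.7 FPKM (SD, n = 3). Their log2 changes were 5.35 ± 0.25 and 5.42 ± 0.28 (limma, Benjamini-Hochberg adjusted p = 3.3e-06 and 6.3e-06). The genes lie on chromosome 17 at 34969190 to 34972156 (ENSMUSG00000091971) and 34956436 to 34959238 (ENSMUSG00000090877), and as close paralogs they can share reads. Npas4, an activity-dependent transcription factor of neurons, rose from 11.7 ± 5.99 to 282 ± 229 FPKM, Atf3, a stress-induced transcription factor, from 0.203 ± 0.0807 to 11.2 ± 5.28 FPKM, and Gadd45g, a growth arrest and DNA damage gene, from 11.5 ± 2.58 to 196 ± 215 FPKM. Their log2 changes were 4.25 ± 0.65, 3.26 ± 0.37 and 3.42 ± 0.57 (adjusted p = 0.021, 0.0054 and 0.031). Fosb, a subunit of the AP-1 transcription factor, rose by 3.28 ± 0.61 in log2 (adjusted p = 0.046).

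The other genes among the 8 largest rises were noncoding. Rn7sk, the 7SK small nuclear RNA, rose from 5.24 ± 3.71 to 245 ± 248 FPKM (log2 change 4.96 ± 0.60, adjusted p = 0.007). Gm26917, a long noncoding RNA gene, rose from 2.66 ± 1.42 to 69.6 ± 51.6 FPKM (4.03 ± 0.50, adjusted p = 0.0084). Among the 8 largest falls, the microRNA gene Mir421 fell from 36.9 ± 3.84 to 9.51 ± 1.86 FPKM (-1.86 ± 0.26, adjusted p = 0.017) and the zinc finger gene Zkscan16 from 8.89 ± 0.359 to 2.73 ± 1.27 FPKM (-1.47 ± 0.23, adjusted p = 0.022). Sox18, a transcription factor of endothelial cells, fell from 3.41 ± 0.27 to 1.20 ± 0.289 FPKM (-1.01 ± 0.17, adjusted p = 0.03), and Gm38020 changed by -1.08 ± 0.17. The rest were Mir208a, Gm23257, Gm42672 and Gm25540, genes shorter than 500 bases with control means of 2.20 to 4.04 FPKM, and Gm25540 was listed at 0 in all 1.5 h libraries. Of all 24 genes that fell, 8 were shorter than 500 bases.

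Immediate early genes, the fast transcriptional response of neurons and other cells to stimulation, were higher as a group. Of the 30 tested, 8 rose, or 19 adjusted over the list alone: Npas4, Fosb, Jun, Maff, Egr4, Arc, Dusp5 and Bdnf. Jun rose from 16.1 ± 1.41 to 57.3 ± 9.69 FPKM (1.76 ± 0.16, adjusted p = 0.00079) and Maff by 1.48 ± 0.21 (adjusted p = 0.017), while Fos had a log2 change of 2.70 ± 0.69 that did not pass (adjusted p = 0.086). The list had a median log2 change of 1.30 (camera adjusted p = 3.82e-11, and adjusted p = 0.736 with an estimated correlation). Its medians in replicates 1, 2 and 3 were 1.05, 1.15 and 1.65 against the control mean, with controls at -0.33 to 0.29. Of 20 heat shock and chaperone genes, 6 rose, or 15 adjusted over the list alone: Hspa1a, Hspa1b, Hspb1 (2.49), Dnajb1 (2.05), Bag3 (1.14) and Dnaja1 (0.90). Their median was 0.78 (adjusted p = 7.11e-10, and adjusted p = 0.497 with an estimated correlation), and the library medians were 1.07, 0.34 and 0.77. The list's median was 0.28 after quantile normalization and 0.46 in length-corrected values (camera adjusted p = 1.79e-12 in the latter).

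Among 22 NF-kB cytokines and chemokines, Ptgs2, the inducible cyclooxygenase, rose from 2.53 ± 1.01 to 23.9 ± 16.2 FPKM (2.66 ± 0.39, adjusted p = 0.021) and Relb, an NF-kB subunit, from 1.16 ± 0.232 to 3.6 ± 1.35 FPKM (1.06 ± 0.20, adjusted p = 0.048). None of the other 20 passed, and 10 rose adjusted over the list alone. The list's median was 0.37 (adjusted p = 0.00351, and adjusted p = 0.736 with an estimated correlation). In length-corrected values it was -0.01, and the list did not pass (camera adjusted p = 0.136). In the heme and porphyrin list, 1 of 20 genes rose, or 2 adjusted over the list alone: Alad, the enzyme that converts 5-ALA, went from 12.2 ± 2.89 to 33.1 ± 11.7 FPKM (1.32 ± 0.24, adjusted p = 0.046). In length-corrected values its change was 0.78 (adjusted p = 0.069). Changes of Alas1, which makes 5-ALA (0.37 ± 0.13, adjusted p = 0.1), Fech, which inserts iron into protoporphyrin IX (-0.02 ± 0.11, adjusted p = 0.94), and Hmox1, heme oxygenase 1 (1.78 ± 0.59, adjusted p = 0.099), did not pass. The heme list's median was 0.37 (adjusted p = 0.0189, and adjusted p = 0.762 with an estimated correlation). Its library medians were 0.75, -0.02 and 0.44 in replicates 1, 2 and 3. In length-corrected values the list's median was 0.16, and it still passed (camera adjusted p = 0.0107).

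Ribosomal protein genes and nuclear genes of oxidative phosphorylation, both made up mostly of short genes, had medians of 1.24 and 1.18 (adjusted p = 2.75e-09 and 2.41e-08, and adjusted p = 0.762 for both with an estimated correlation). None of 27 members passed in either list, and 26 and 25 did adjusted over the list alone. Their medians were 2.20 and 2.14 in replicate 1 and 1.51 and 1.41 in replicate 3, the libraries with the length trend, and 0.10 and 0.04 in replicate 2. In length-corrected values the list medians were 0.69 and 0.64 (camera adjusted p = 3.49e-13 and 1.79e-12). Tight junction and barrier transporter genes had a median of -0.27 (adjusted p = 0.0027, and adjusted p = 0.762 with an estimated correlation), with 0 of 19 passing and 3 adjusted over the list alone. Slco1a4 and Abcb1a, transporters of brain endothelium, had changes of -1.19 ± 0.27 and -1.0 ± 0.28 (adjusted p = 0.078 and 0.088). This list's library medians were -0.51, -0.09 and -0.30. In length-corrected values its median was -0.43, and it still passed (camera adjusted p = 0.0206). Endothelial markers had a median of -0.44 (camera adjusted p = 0.0773) and library medians of -0.36, -0.04 and -0.69. Pericyte and smooth muscle markers had a median of -0.30 (adjusted p = 0.25) and library medians of -0.42, 0.03 and -0.57. Lists of ER stress (median 0.46), activated microglia (0.38), glutamate receptors (-0.25), choroid plexus (-0.70) and thalamus (-0.75) also passed (adjusted p = 0.00232, 0.024, 0.00322, 0.0189 and 0.0189), and none of these did with an estimated correlation. In length-corrected values their medians were 0.10, 0.14, -0.11, -1.22 and -0.58, and none passed (adjusted p = 0.0751, 0.238, 0.741, 0.0914 and 0.262). Thalamus markers lay at -0.36, -0.49 and 0.91 in control replicates 1, 2 and 4 and at -0.42, -0.65 and -0.39 at 1.5 h. Atf3 was the only member of these lists that passed. Gfap, the intermediate filament of astrocytes, was at 20.3 ± 6.97 FPKM in controls and 22.4 ± 11.7 FPKM at 1.5 h (0.02 ± 0.40, adjusted p = 0.98).

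At 1.5 h, 74 genes rose and 24 fell of 17664 tested (limma, FDR 0.05), 51 and 12 of them by at least 2-fold, and 12 of 44 lists passed. In length-corrected values 42 rose and 34 fell. The count of 98 was 23 without replicates 1 and 3, 8071 without replicate 2, 30 and 27 without replicates 1 and 3 in turn, 11, 11 and 21 without control replicates 1, 2 and 4, and 5 with only the 2 groups in the fit. Hspa1a and Hspa1b kept their calls in every alternative run, and every gene named as a fall lost its call in 1 or more. Only 3 genes rose with the replicate block and 4 with only the 2 groups in the fit, so most of the other named rises lost their calls there too.

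The comparison of 12 h with control asks what differed at the middle time. Hspa1b and Hspa1a were again the largest rises, at 2190 ± 104 and 1430 ± 62.6 FPKM (SD, n = 3), with log2 changes of 9.08 ± 0.28 and 8.87 ± 0.25 (limma, adjusted p = 2.3e-08 and 1.3e-08). Atf3 reached 150 ± 23.8 FPKM (6.96 ± 0.37, adjusted p = 1.5e-06, chromosome 1, 191170296 to 191218039, ENSMUSG00000026628), Npas4 981 ± 215 FPKM (6.34 ± 0.65, adjusted p = 8e-05), Gadd45g 794 ± 170 FPKM (5.99 ± 0.57) and Fosb 222 ± 22.8 FPKM (5.78 ± 0.61). The chemokines Ccl3 and Ccl4 rose from 0.0249 ± 0.0431 to 60.5 ± 3.92 FPKM and from 0.0286 ± 0.0496 to 66.5 ± 4.52 FPKM, with log2 changes of 5.91 ± 0.53 and 6.04 ± 0.67 (adjusted p = 4e-05 and 0.00013). In the other direction, P2ry12, a purinergic receptor of resting microglia, fell from 12.7 ± 1.87 to 0.692 ± 0.0204 FPKM (-3.0 ± 0.22, adjusted p = 9.7e-06, chromosome 3, 59216272 to 59262871, ENSMUSG00000036353).

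The 8 largest falls also held Tmem119, another microglial marker (-2.02 ± 0.24, adjusted p = 0.0002), and Rph3a, which encodes the synaptic vesicle protein rabphilin (63.4 ± 28.7 to 3.51 ± 0.175 FPKM, -3.75 ± 0.55, adjusted p = 0.00078). Dbp, a clock-controlled transcription factor, fell from 36.2 ± 12.3 to 7.49 ± 1.78 FPKM (-2.09 ± 0.30, adjusted p = 0.00064) and Itm2a, expressed by endothelium, changed by -1.98 ± 0.21 (adjusted p = 9.9e-05). Of 17 circadian clock genes 3 rose and 5 fell by either adjustment, and the list did not pass (median -0.01, camera adjusted p = 0.628). The time of day of collection is not given, and its part in these changes at 12 h was not tested. Adora2a, the adenosine receptor of striatal neurons, fell from 21.3 ± 9.75 to 4.33 ± 1.70 FPKM (-2.03 ± 0.51, adjusted p = 0.016), a call lost without control replicate 2 or 12 h replicate 2. Striatum markers as a list did not pass (median -0.22, adjusted p = 0.726), with library medians of -0.44 to 0.50 in controls. The microRNA gene Mir421 (-2.79 ± 0.26) and the pseudogene Gm13443 (-3.32 ± 0.94) complete the 8, and Gm13443 lost its call when any of the 6 libraries was left out.

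Stress and signalling lists rose at 12 h. Of 30 immediate early genes, 25 rose, or 28 adjusted over the list alone (median 2.71, adjusted p = 1.9e-19, and adjusted p = 0.117 with an estimated correlation), Maff by 3.85 ± 0.21 and Jun by 2.74 ± 0.16 among them. Of 20 heat shock and chaperone genes, 15 rose, or 17 adjusted over the list alone (median 1.20, adjusted p = 2.06e-14, and adjusted p = 0.0646 with an estimated correlation). In the p53 and apoptosis list 11 of 19 rose, or 11 with 1 falling adjusted over the list alone. Examples were Gadd45a at 1.84 ± 0.19 and Cdkn1a, the p21 inhibitor of cell division, at 3.12 ± 0.35 (median 0.47, adjusted p = 5.03e-05, and adjusted p = 0.0362 with an estimated correlation). Bbc3 and Apaf1, named by the rule as the falling members with the smallest p, had changes of -0.26 ± 0.24 and -0.35 ± 0.13 that did not pass. Among 16 glucocorticoid targets 11 rose, or 13 adjusted over the list alone, with Errfi1 at 2.67 ± 0.19 (median 0.99, adjusted p = 2.22e-06, and adjusted p = 0.242 with an estimated correlation). Of 13 hypoxia targets 7 rose and 1 fell, by either adjustment: Adm, a vasodilator peptide, rose by 2.51 ± 0.22 and Pfkfb3, a glycolytic regulator, by 1.51 ± 0.18, and Pdk1 changed by -0.57 ± 0.16 (median 0.53, adjusted p = 0.0053, and adjusted p = 0.0905 with an estimated correlation).

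Of 21 oxidative stress and NRF2 targets, 8 rose, or 8 with 1 falling adjusted over the list alone. Hmox1 went from 2.48 ± 0.391 to 39.0 ± 6.28 FPKM (3.51 ± 0.59, adjusted p = 0.0017) and Srxn1, which repairs peroxiredoxins, from 32.6 ± 2.19 to 98.8 ± 11.2 FPKM (1.57 ± 0.17, adjusted p = 0.00012). Nqo1, another known NRF2 target, was at 2.38 ± 0.471 and 1.71 ± 0.148 FPKM (-0.31 ± 0.21, adjusted p = 0.34). The list's median was 0.17 (adjusted p = 0.0129, and adjusted p = 0.621 with an estimated correlation). Of 19 ER stress and ATF4 targets 7 rose by either adjustment, Chac1 by 1.97 ± 0.17 (median 0.35, adjusted p = 0.0053, and adjusted p = 0.621 with an estimated correlation). In the heme list 4 of 20 genes rose, or 6 with 2 falling adjusted over the list alone, and the list did not pass (median -0.01, adjusted p = 0.73). Alas1 and Fech had changes of -0.08 ± 0.13 and -0.31 ± 0.11 (adjusted p = 0.71 and 0.067).

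NF-kB and reactive astrocyte genes rose at 12 h as well. Of 22 NF-kB cytokines and chemokines, 20 rose by either adjustment, with Socs3, an inhibitor of cytokine signalling, at 3.84 ± 0.25 and Ptgs2 at 4.90 ± 0.39 (median 1.72, adjusted p = 1.47e-16, and adjusted p = 0.0311 with an estimated correlation). Ccl5 and Cxcl10 were the members that did not pass (-0.02 and 0.28). Reactive astrocyte genes rose in 21 of 23 by either adjustment (median 1.87, adjusted p = 5.8e-17, and adjusted p = 0.0773 with an estimated correlation), with Gfap at 162 ± 19.2 FPKM (2.99 ± 0.40, adjusted p = 0.00044) and Emp1 at 3.31 ± 0.24. Of 18 endothelial activation and remodelling genes, 14 rose by either adjustment (median 1.03, adjusted p = 2.44e-09, and adjusted p = 0.167 with an estimated correlation), among them Angpt2, a vascular growth factor released by endothelium (2.96 ± 0.16), and Timp1, a protease inhibitor (2.75 ± 0.23). Plvap, a protein of leaky vessels, was at 9.49 ± 0.584 FPKM against 7.50 ± 0.606 FPKM in controls (0.30 ± 0.22, adjusted p = 0.37). Among 15 endothelial markers 6 rose and 1 fell, or 7 and 2 adjusted over the list alone, with Ly6a at 3.69 ± 0.33 (median 0.49, adjusted p = 0.0129, and adjusted p = 0.753 with an estimated correlation). The interferon list had 5 of 22 rising, or 6 with 1 falling adjusted over the list alone, and MHC and complement 7 of 16, or 8. Their medians were 0.34 and 0.51 (adjusted p = 0.0171 and 0.0053, and adjusted p = 0.821 and 0.617 with an estimated correlation).

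Microglial genes moved in both directions at 12 h. Of 14 homeostatic microglia markers, 10 fell and 1 rose, or 10 and 2 adjusted over the list alone (median -0.74, adjusted p = 7.39e-05, and adjusted p = 0.277 with an estimated correlation). Beside P2ry12 and Tmem119 the falls included Selplg (-1.90) and Gpr34 (-1.63). Of 16 genes of activated microglia and phagocytes, 7 rose by either adjustment, with Cd14, a co-receptor for bacterial lipopolysaccharide, from 1.74 ± 0.403 to 92.2 ± 16.7 FPKM (5.08 ± 0.35, adjusted p = 6.6e-06) and Cd86 by 1.33 ± 0.12. Aif1 and Trem2 had changes of -0.30 ± 0.36 and -0.36 ± 0.26 that did not pass. The activated list's median was 0.52 (adjusted p = 5.83e-05, and adjusted p = 0.291 with an estimated correlation).

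Barrier, myelin and glutamate receptor lists differed in direction at 12 h. Of 19 tight junction and barrier transporter genes, 7 rose and 3 fell, or 8 and 5 adjusted over the list alone, and the list did not pass (median 0.33, adjusted p = 0.354). Cldn5, the main claudin of brain endothelium, rose from 14.3 ± 0.997 to 27.6 ± 2.08 FPKM (0.90 ± 0.15, adjusted p = 0.0014), and in length-corrected values its change was 0.93 (adjusted p = 0.062). The falls were in the transporters Slc22a8 (-1.64), Slco1a4 (-1.57) and Abcb1a (-0.98), and Ocln and Tjp1 had changes of -0.08 ± 0.19 and 0.53 ± 0.24 (adjusted p = 0.82 and 0.15). Of 14 myelin genes 4 rose by either adjustment: Mobp (1.38 ± 0.33), Cldn11 (1.36 ± 0.35), Mal (1.22) and Tspan2 (0.77), with a list median of 0.67 (adjusted p = 0.0129, and adjusted p = 0.832 with an estimated correlation). In the lymphatic list 4 of 7 genes rose by either adjustment, Pdpn by 1.77 ± 0.18 and Flt4 by 0.60 ± 0.15 among them (median 0.60, adjusted p = 0.0242, and adjusted p = 0.427 with an estimated correlation). Of 17 glutamate receptor genes 5 fell, or 6 adjusted over the list alone, with Grm2 at -0.94 ± 0.16 and Grm3 at -0.78 ± 0.15 (median -0.36, adjusted p = 0.0129, and adjusted p = 0.753 with an estimated correlation).

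At 12 h, 2342 genes rose and 1395 fell (limma, FDR 0.05), 865 and 124 of them by at least 2-fold, and 18 of 44 lists passed. The count of 3737 was 6211 without 1.5 h replicates 1 and 3, 7279 with only the 2 groups in the fit and 2326, 2293 and 2393 without control replicate 1, control replicate 2 or 12 h replicate 2. After quantile normalization, which shifted the median of all genes by -0.08, 2175 genes rose and 2431 fell.

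**Figure D2:**
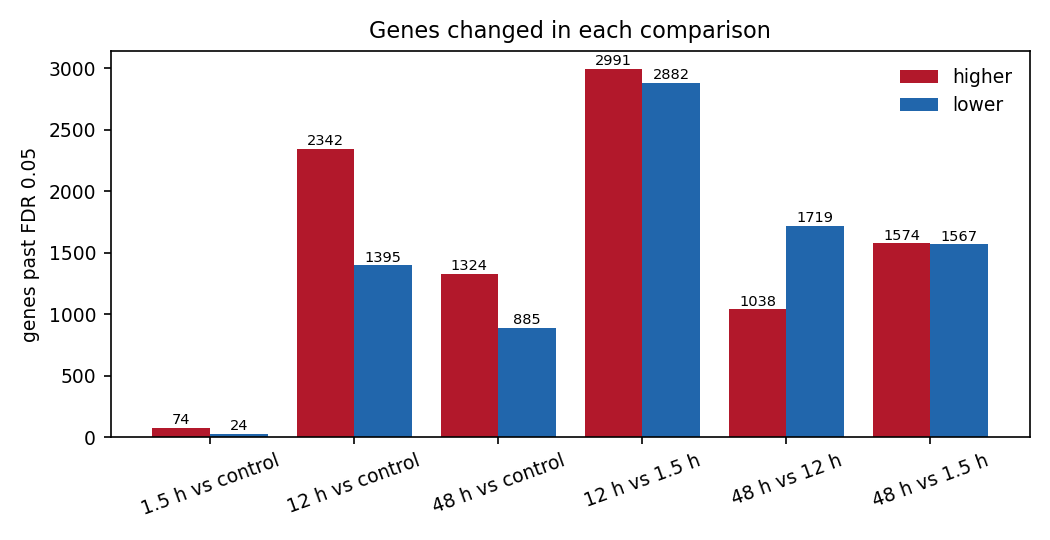
Number of genes past an FDR of 0.05 (vertical axis) in each of the 6 comparisons (horizontal axis), with red bars for genes higher and blue bars for genes lower in the group named first. The fewest stood at 1.5 h against control, with 74 higher and 24 lower.

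The comparison of 48 h with control covers the latest time. Glial and phagocyte genes were among the largest rises. Spp1, which encodes osteopontin, rose from 1.77 ± 1.51 to 587 ± 465 FPKM (SD, n = 3, log2 change 7.55 ± 0.51, limma adjusted p = 7.3e-06, chromosome 5, 104435118 to 104441050, ENSMUSG00000029304). Gfap reached 534 ± 97.2 FPKM (4.69 ± 0.40, adjusted p = 3.3e-05, chromosome 11, 102887336 to 102900912, ENSMUSG00000020932), and Vim, the filament protein vimentin, 143 ± 39.8 FPKM from 4.22 ± 0.824 FPKM (4.76 ± 0.23, adjusted p = 1.2e-06). Timp1 rose to 54.3 ± 10.8 FPKM (5.08 ± 0.23, adjusted p = 1.1e-06), and the neuropeptide galanin, encoded by Gal, from 0.91 ± 0.82 to 64.8 ± 16.2 FPKM (5.16 ± 0.33, adjusted p = 6e-06). The remaining 3 of the 8 largest rises were Tgm1 (4.47 ± 0.31), the tubulin gene Tubb6 (3.97 ± 0.17) and S100a11 (3.94 ± 0.26).

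Neuronal signalling genes were among the largest falls. The receptor genes Gpr6 (-2.05 ± 0.34, adjusted p = 0.0025) and Adora2a (-1.98 ± 0.51, adjusted p = 0.027), both known from striatal neurons, fell. The kinase gene Camkk2 fell from 33.3 ± 7.32 to 7.35 ± 0.996 FPKM (-2.02 ± 0.30, adjusted p = 0.0015). Hlf, a clock-controlled transcription factor, fell from 34.9 ± 5.26 to 8.0 ± 1.93 FPKM (-2.01 ± 0.29, adjusted p = 0.0012), and Tcap, Frzb and Ankrd63 changed by -2.33 ± 0.26, -2.08 ± 0.23 and -1.93 ± 0.43. Of 14 striatum markers 4 fell by either adjustment (median -0.69, adjusted p = 0.000829, and adjusted p = 0.475 with an estimated correlation). This list's library medians were -0.43, -1.19 and -0.92 at 48 h and -0.44, 0.50 and -0.08 in the controls. Adora2a and Ankrd63 lost their calls without control replicate 2, 48 h replicate 3 or 48 h replicate 4, and Adora2a also without control replicates 1 or 4.

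**Figure D3:**
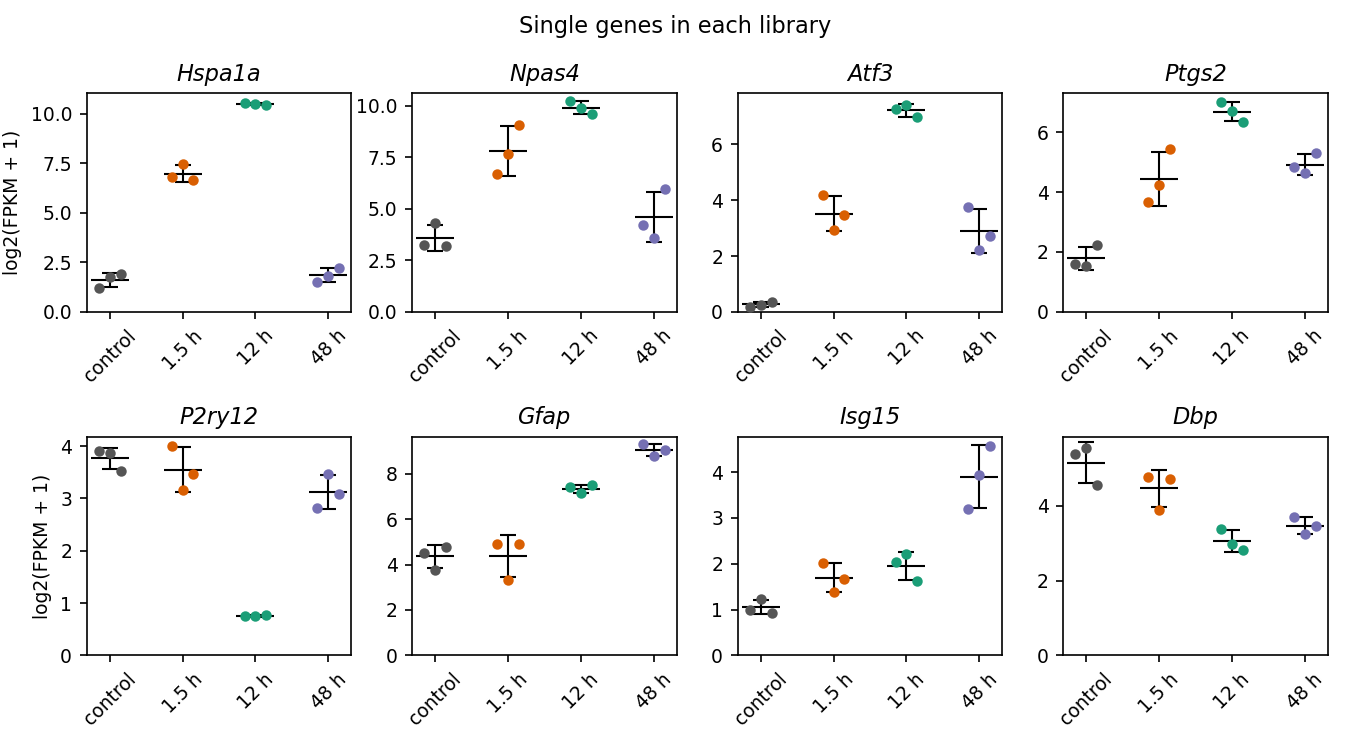
Level of 8 genes as log2(FPKM + 1) (vertical axes) in the control, 1.5 h, 12 h and 48 h groups (horizontal axes), with 1 point per library and bars for the mean ± SD of 3 libraries on this scale. Hspa1a, Npas4, Atf3 and Ptgs2 were highest at 12 h, Gfap and Isg15 at 48 h, and P2ry12 and Dbp were lowest at 12 h.

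Glial and immune lists led the rises at 48 h. Reactive astrocyte genes rose in 18 of 23, or 19 adjusted over the list alone (median 2.29, adjusted p = 7.74e-23, and adjusted p = 0.0651 with an estimated correlation). Of 14 astrocyte markers, Aqp4, the water channel of astrocytes, rose from 11.7 ± 1.79 to 34.2 ± 9.92 FPKM (1.44 ± 0.21, adjusted p = 0.0011) and Aldh1l1 by 0.86 ± 0.10. In the same list Slc39a12 (-1.05 ± 0.16), Gpc5 (-0.79 ± 0.11), Ntsr2 (-1.06) and Aldoc (-0.74) fell (2 and 7 adjusted over the list alone, median -0.38, adjusted p = 0.0242, and adjusted p = 0.427 with an estimated correlation). Interferon response genes rose in 21 of 22 by either adjustment, with Isg15 from 1.08 ± 0.234 to 15.1 ± 7.31 FPKM (2.85 ± 0.30, adjusted p = 0.00014) and Ifitm3 at 2.87 ± 0.28 (median 1.16, adjusted p = 3.19e-17, and adjusted p = 0.115 with an estimated correlation). MHC and complement genes rose in 14 of 16, or 15 adjusted over the list alone, with the complement gene C4b at 2.63 ± 0.21 and the MHC class I gene H2-K1 at 1.40 ± 0.14 (median 1.15, adjusted p = 5.09e-14, and adjusted p = 0.0651 with an estimated correlation). All 16 tested proliferation genes rose by either adjustment, Mcm3 by 1.57 ± 0.20 and Cdk1, a cell cycle kinase, by 1.37 ± 0.14 (median 1.03, adjusted p = 1.85e-14, and adjusted p = 0.187 with an estimated correlation). Their library medians were 1.51, 0.80 and 0.75 in replicates 1, 3 and 4.

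Of 16 genes of activated microglia and phagocytes, 13 rose, or 14 adjusted over the list alone (median 1.44, adjusted p = 1.58e-11, and adjusted p = 0.0818 with an estimated correlation), with Cd14 at 40.5 ± 1.16 FPKM (3.93) and Cst7, a microglial protease inhibitor, at 4.21 ± 1.35 FPKM (2.24 ± 0.19). Aif1 rose from 3.02 ± 1.09 to 9.47 ± 3.53 FPKM (1.36 ± 0.36, adjusted p = 0.03), a call lost without any 1 of control replicates 1, 2 and 4 and 48 h replicates 3 and 4. Homeostatic microglia markers rose in 6 of 14, or 8 with 2 falling adjusted over the list alone (median 0.64, adjusted p = 0.000569, and adjusted p = 0.277 with an estimated correlation). Olfml3 (2.10 ± 0.12) and Fcrls (2.47 ± 0.29) were among them, and P2ry12 was at 7.86 ± 2.0 FPKM (-0.64 ± 0.22, adjusted p = 0.081). NF-kB cytokines and chemokines rose in 13 of 22, or 15 adjusted over the list alone, with Ccl12 at 3.93 ± 0.18 (median 0.90, adjusted p = 2.86e-10, and adjusted p = 0.0651 with an estimated correlation). Of 5 tested neutrophil and monocyte genes, Lyz2, the lysozyme of macrophages and related cells, rose by 3.63 ± 0.34 (list adjusted p = 0.0177, and adjusted p = 0.45 with an estimated correlation, 2 genes adjusted over the list alone).

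Of 18 endothelial activation and remodelling genes 12 rose, or 13 adjusted over the list alone, with Cav1, a caveolae protein, at 1.92 ± 0.17 (median 0.80, adjusted p = 3.03e-08, and adjusted p = 0.187 with an estimated correlation). Plvap was at 6.01 ± 0.573 FPKM (-0.28 ± 0.22, adjusted p = 0.47). Among 19 tight junction and barrier transporter genes 3 rose, or 5 adjusted over the list alone: Cldn5 to 39.3 ± 5.64 FPKM (1.39 ± 0.15, adjusted p = 0.00014), Slc16a1 (0.77 ± 0.13) and Lsr (0.70), with a list median of 0.17 (adjusted p = 0.0366, and adjusted p = 0.64 with an estimated correlation or 0.0569 in length-corrected values, where the median was 0.23). Of 15 endothelial markers 3 rose, or 7 adjusted over the list alone (median 0.61, adjusted p = 8.35e-05, and adjusted p = 0.4 with an estimated correlation). In replicates 1, 3 and 4 the barrier list lay at 0.41, 0.01 and 0.05 and the endothelial markers at 0.96, 0.23 and 0.36. Replicate 1 also stood apart in markers of choroid plexus (0.87, against -0.72 and -0.66) and myelin (0.70, against -0.36 and -0.30). Ocln and Tjp1 had changes of 0.12 ± 0.19 and -0.04 ± 0.24 (adjusted p = 0.75 and 0.93). In the lymphatic list 2 of 7 genes rose by either adjustment, Pdpn, a glycoprotein also made by other cells, by 2.70 ± 0.18 and Stab1, a scavenger receptor of macrophages and endothelium, by 1.96 ± 0.33 (adjusted p = 0.0116, and adjusted p = 0.277 with an estimated correlation).

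Clock and glutamate receptor genes were lower at 48 h. Of 17 circadian clock genes 11 fell and 1 rose, or 13 and 1 adjusted over the list alone (median -0.85, adjusted p = 1.23e-06, and adjusted p = 0.187 with an estimated correlation). Ciart, a clock repressor, fell from 10.1 ± 1.78 to 3.10 ± 0.924 FPKM (-1.45 ± 0.23, adjusted p = 0.0024), and Nfil3, a transcription factor also induced by cytokines, rose by 1.31 ± 0.28 (adjusted p = 0.011). Glutamate receptor genes fell in 8 of 17, or 11 adjusted over the list alone, with Gria3 at -1.14 ± 0.22 and Grm5 at -0.99 ± 0.18 (median -0.59, adjusted p = 2.53e-06, and adjusted p = 0.277 with an estimated correlation). In the GABA list 2 of 18 fell, or 6 adjusted over the list alone, the receptor gene Gabra4 (-0.72 ± 0.15) among them, with a median of -0.36 (adjusted p = 0.000689, and adjusted p = 0.269 with an estimated correlation). Cortex neuron markers fell in 2 of 15 (median -0.45, adjusted p = 0.0326, and adjusted p = 0.427 with an estimated correlation). In length-corrected values the median was -0.26 (adjusted p = 0.0649). None of 15 pan-neuronal genes passed (median -0.22, adjusted p = 0.0562).

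Heat shock and immediate early genes had smaller list medians at 48 h than at 12 h. Hspa1a was at 2.70 ± 0.907 FPKM (0.24 ± 0.25, adjusted p = 0.59), and of 20 heat shock and chaperone genes 3 rose, Hspb1 (3.49), Hspb8 (1.84) and Bag3 (1.64), and 1 fell, Dnajb1 (-0.58), by either adjustment, while the list did not pass (adjusted p = 0.0676). Of 30 immediate early genes 7 rose, or 10 adjusted over the list alone, with Bdnf, a neurotrophin, at 2.04 ± 0.21 and Jun at 1.11 ± 0.16 (median 0.56, adjusted p = 0.000683, and adjusted p = 0.467 with an estimated correlation). Hmox1 was at 44.4 ± 47.4 FPKM (3.20 ± 0.59, adjusted p = 0.0049) and Srxn1 at 89.0 ± 12.6 FPKM (1.42 ± 0.17). In the heme list 5 of 20 genes rose and 1 fell, or 6 and 1 adjusted over the list alone, with Tspo, a mitochondrial membrane protein used as a marker of reactive glia, at 2.58 ± 0.21 and the peptide transporter gene Slc15a2 at -0.52 ± 0.14 (median 0.20, adjusted p = 0.0309, and adjusted p = 0.467 with an estimated correlation). Lists of NRF2 targets (5 of 21 rose, or 8 adjusted over the list alone), ER stress (5 of 19, or 8), p53 and apoptosis (5 of 19, or 6) and hypoxia (2 of 13, or 4) passed as well, with medians of 0.37, 0.47, 0.35 and 0.21 (hypoxia 0.11 in length-corrected values). Their adjusted p were 0.00227, 2.94e-05, 0.000931 and 0.0483, and 0.369, 0.277, 0.0651 and 0.227 with an estimated correlation. Alas1 and Fech had changes of 0.01 ± 0.13 and 0.05 ± 0.11 (adjusted p = 0.96 and 0.84).

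Ribosomal and pericyte lists also passed at 48 h. None of 27 cytosolic ribosomal proteins passed by either adjustment, while the list did (median 0.65, adjusted p = 0.000829, and adjusted p = 0.64 with an estimated correlation), with library medians of 0.48, 1.01 and 0.43. In length-corrected values its median was 0.51 (adjusted p = 4.26e-05). Of 9 pericyte and smooth muscle markers, Acta2 (0.87) and Kcnj8 (0.66) rose by either adjustment (median 0.29, adjusted p = 0.0177, and adjusted p = 0.467 with an estimated correlation). This list's library medians were 0.74, -0.03 and 0.13, and it did not pass in length-corrected values (median 0.30, adjusted p = 0.0521) or without 48 h replicate 1 (adjusted p = 0.232).

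At 48 h, 1324 genes rose and 885 fell (limma, FDR 0.05), 569 and 161 of them by at least 2-fold, and 26 of 44 lists passed. The count of 2209 was 4682 without 1.5 h replicates 1 and 3, 3789 with only the 2 groups in the fit, and 1241 and 1206 without control replicates 1 and 2.

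**Figure D4:**
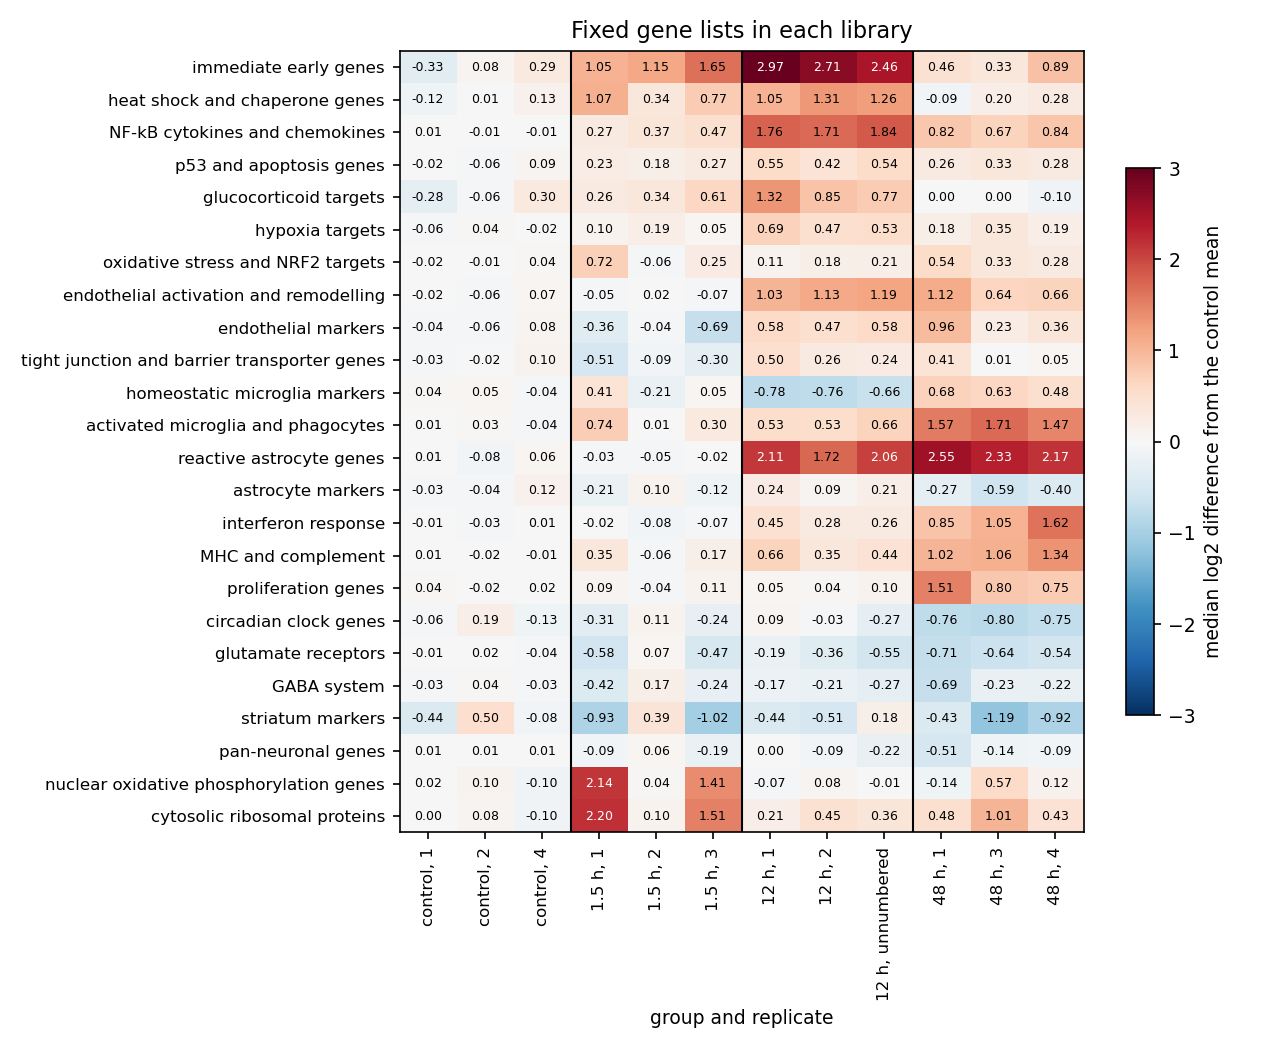
Median log2 difference from the control mean (colour and printed value) of 24 of the gene lists (vertical axis) in each of the 12 libraries, ordered by group and replicate (horizontal axis). Reactive astrocyte genes lay at 1.72 to 2.11 in the 12 h libraries and 2.17 to 2.55 in the 48 h libraries, against -0.08 to 0.06 in the controls.

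The comparison of 12 h with 1.5 h covers the change between the first times. Spp1 rose by 6.27 ± 0.51 in log2 (limma, adjusted p = 4.9e-05), the activin subunit gene Inhba from 2.02 ± 1.01 to 51.0 ± 26.6 FPKM (4.01 ± 0.40, adjusted p = 0.00012) and the neuropeptide gene Nts from 4.77 ± 3.56 to 75.7 ± 42.9 FPKM (3.85 ± 0.57, adjusted p = 0.00093), with Ccl3 and the noncoding gene Gm20005 completing the 5 largest rises (3.98 ± 0.53 and 4.38 ± 0.41). P2ry12 (-2.79 ± 0.22), Crybb1 (-2.78 ± 0.27), Tmem119 (-2.38 ± 0.24) and Selplg (-2.25 ± 0.25), all expressed by microglia, fell. Rps27rt changed by -2.31 ± 0.64 (adjusted p = 0.02), a call lost without 1.5 h replicates 1 or 3, which carry the length trend. Immediate early genes rose in 19 of 30 and heat shock and chaperone genes in 11 of 20 (adjusted p = 3.04e-07 and 2.39e-05, and adjusted p = 0.542 and 0.448 with an estimated correlation), or 21, with 1 falling, and 11 adjusted over the list alone. NF-kB cytokines and chemokines rose in 17 of 22 and reactive astrocyte genes in 21 of 23 by either adjustment (adjusted p = 2.04e-09 and 4.3e-14, and adjusted p = 0.159 for both with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 15 of 27, or 24 adjusted over the list alone (median -1.24, adjusted p = 2.76e-06, and adjusted p = 0.854 with an estimated correlation), beside the length trend of 1.5 h replicates 1 and 3, and the median was -0.55 in length-corrected values.

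In total 2991 genes rose and 2882 fell from 1.5 h to 12 h, and 17 of 44 lists passed. In length-corrected values 4031 rose and 2106 fell. The count of 5873 was 2409 without 1.5 h replicates 1 and 3, 9667 without replicate 2, 3782 and 3408 without replicates 1 and 3 in turn, 3805, 3706 and 3667 without each of the 12 h libraries, and 2384 with only the 2 groups in the fit.

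Between 12 h and 48 h heat shock and immediate early genes fell, and homeostatic microglia and proliferation genes rose. Hspa1b and Hspa1a changed by -8.97 ± 0.28 and -8.63 ± 0.25 (limma, adjusted p = 2.6e-08 and 1.7e-08) and Npas4 by -5.32 ± 0.65 (adjusted p = 0.0004). The pseudogene Gm8696, which lies beside Hspa1b on chromosome 17 at 34954328 to 34954712, and Gm20005 changed by -5.12 ± 0.44 and -4.66 ± 0.41. Rises were largest in Gal (4.30 ± 0.33, adjusted p = 2.9e-05), Gm13443 (3.89 ± 0.94, adjusted p = 0.017), Rph3a (3.11 ± 0.55, adjusted p = 0.0034), the protease gene Klk6 (3.06 ± 0.38, adjusted p = 0.00042) and Trh, which encodes thyrotropin-releasing hormone (2.99 ± 0.24, adjusted p = 3.2e-05). Immediate early genes fell in 24 of 30 and heat shock and chaperone genes in 13 of 20 (adjusted p = 2.43e-16 and 7.84e-13, and adjusted p = 0.183 and 0.134 with an estimated correlation), or 26, with 1 rising, and 17 adjusted over the list alone. Homeostatic microglia markers rose in 11 of 14 by either adjustment (median 1.54, adjusted p = 7.84e-13, and adjusted p = 0.134 with an estimated correlation). Interferon response genes rose in 16 of 22 and proliferation genes in 15 of 16, or 19 and 16 adjusted over the list alone (adjusted p = 6.31e-11 and 6.91e-13, and adjusted p = 0.228 for both with an estimated correlation). Of 16 glucocorticoid targets 10 fell, or 13 adjusted over the list alone (adjusted p = 6.79e-08, and adjusted p = 0.183 with an estimated correlation).

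From 12 h to 48 h, 1038 genes rose and 1719 fell, and 15 of 44 lists passed. After quantile normalization 1693 rose and 1723 fell. The count of 2757 was 5405 without 1.5 h replicates 1 and 3, 1772, 1614 and 1820 without 12 h replicates 1 and 2 and 48 h replicate 4, and 1707 without 48 h replicate 3. Gm13443 lost its call without 12 h replicate 2, the unnumbered library or 48 h replicates 3 or 4.

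From 1.5 h to 48 h, Spp1 rose by 8.05 ± 0.51 (limma, adjusted p = 6e-06), Gal by 5.11 ± 0.33, Timp1 by 5.06 ± 0.23, Vim by 4.74 ± 0.23 and Gfap by 4.67 ± 0.40 (adjusted p = 3.8e-05). Hspa1b and Hspa1a changed by -5.31 ± 0.28 and -5.11 ± 0.25, Rn7sk by -3.97 ± 0.60, Npas4 by -3.22 ± 0.65 (adjusted p = 0.007) and Tcap by -2.80 ± 0.26. Interferon response genes rose in 21 of 22 by either adjustment and tight junction and barrier transporter genes in 6 of 19, or 13 adjusted over the list alone (adjusted p = 1.84e-16 and 7.27e-06, and adjusted p = 0.255 and 0.428 with an estimated correlation). The barrier list's median was 0.54. Medians were 0.96 for endothelial, 0.70 for pericyte and smooth muscle and 0.82 for meningeal fibroblast markers. These lists passed too (camera adjusted p = 4.1e-07, 0.00306 and 0.00503, and 0.39, 0.476 and 0.428 with an estimated correlation). In all, 1574 genes rose and 1567 fell, or 2285 and 1320 in length-corrected values, and 20 of 44 lists passed. The count of 3141 was 7812 without 1.5 h replicate 2, 1877, 1940 and 1944 without 1.5 h replicate 3, 48 h replicate 1 or 48 h replicate 4, and 559 with only the 2 groups in the fit.

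Across the 4 groups together, limma's overall test called 6786 genes. Of the genes called against control, 686 rose and 386 fell at both 12 h and 48 h, and 29 were called in opposite directions. Independent lists of these sizes would share 175.5 and 69.9 genes. At 1.5 h and 12 h, 58 rose and 15 fell in both, against 9.8 and 1.9 for independent lists, and at 1.5 h and 48 h 35 and 10, against 5.5 and 1.2. All 3 comparisons use the same 3 controls, so part of the overlap can come from them. In 50 simulations of unchanged groups against shared controls, the log2 changes correlated at 0.498 or 0.499 across genes and the mean number of shared calls was 0. Unchanged groups give hardly any calls to share, so this 0 does not show how much the shared controls add to the overlap. The observed correlations were 0.297 for 1.5 h and 12 h, 0.379 for 1.5 h and 48 h and 0.547 for 12 h and 48 h. The covariances were 0.082, 0.091 and 0.159 in the same order, against 0.027 in the simulations. In every list past the threshold, the median, the mean and the direction of the test had the same sign.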

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

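In this part, the tests of the length correction, both tests of the microglial pattern and the test of neuron loss were chosen after the result was seen.

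Lists and genes named here moved in opposite directions from control at 2 times, and limma was used to compare those times directly. The barrier list, the homeostatic microglia list and the single genes were picked because this difference also passed the threshold. The adjusted p-values that passed are therefore part of the choice and not a separate test. Tight junction and barrier transporter genes had a median log2 change of -0.27 at 1.5 h and 0.17 at 48 h, and 0.54 for 48 h against 1.5 h (camera, Benjamini-Hochberg adjusted p = 7.27e-06). This list's library medians were -0.51, -0.09 and -0.30 at 1.5 h and 0.41, 0.01 and 0.05 in 48 h replicates 1, 3 and 4. At 1.5 h 0 of its 19 genes passed, and at 48 h it did not pass in length-corrected values (median 0.23, adjusted p = 0.0569). Endothelial markers had medians of -0.44, 0.61 and 0.96 in the same order, and pericyte and smooth muscle markers -0.30, 0.29 and 0.70. Neither passed at 1.5 h. Homeostatic microglia markers had a median log2 change of -0.74 at 12 h and 0.64 at 48 h, and 1.54 between these times (adjusted p = 7.84e-13). With an estimated correlation, the adjusted p of the difference was 0.428 for the barrier list and 0.134 for the homeostatic list. Crybb1, which microglia express, had 1.75 at 1.5 h and -1.03 at 12 h, a difference of -2.78 (adjusted p = 0.00011). Olfml3, another microglial gene, had -0.40 at 12 h and 2.10 at 48 h, a difference of 2.50 (adjusted p = 1.4e-06). Sox18, an endothelial transcription factor, had -1.01 at 1.5 h and 0.82 at 48 h, a difference of 1.84 (adjusted p = 5.4e-05).

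Ribosomal protein and oxidative phosphorylation genes were higher at 1.5 h in replicates 1 and 3, with medians over the 54 genes of 2.17 and 1.43, and not in replicate 2 (0.05). The test of replicate 2, chosen beforehand, came out as the length trend predicts. After correction for the deposited gene length the median in replicates 1 and 3 was 0.93 (quartiles 0.68 to 1.16). Before correction it was 1.79. In 1000 random sets of genes matched on deposited length and level, the median was 0.92 and the 95th percentile 1.11. These values argue against deposited length and level as the whole cause. Deposited length had a median of 1919 bases in the 54 genes and 3516 in all tested genes. Whether it matches the length of the RNA sequenced was not tested, so these values cannot decide about a trend with RNA length, which stays open. A difference in RNA quality or library preparation, which the labels do not give, and a response in the tissue of 2 of the 3 libraries stay open as possible explanations.

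Homeostatic microglia markers were lower at 12 h, with a median of -0.74. The other 9 microglial genes had a median of 1.13 (quartiles 0.21 to 1.2). C1qa, C1qb and C1qc came from the MHC and complement list and the rest from the activated microglia list. Both lists had already passed as higher at 12 h, so this test cannot decide about the share of microglia. The values show only that not all microglial genes fell together. Of the 9 genes, Cd68 (1.92), Fcer1g (1.48), C1qb (1.20) and C1qc (1.13) passed, and Tyrobp (1.13), C1qa (0.63), Ctss (0.21), Aif1 (-0.30) and Trem2 (-0.36) did not. After length correction the median of the homeostatic list was -0.72, but the correction moved all genes of this comparison by a median of only 0.02, so this test decides nothing about the length trend. A change of state in microglia may explain the pattern, and replacement by infiltrating phagocytes stays open, since both would lower these markers and raise the others. A lower share of microglia beside such a change stays open too.

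Circadian clock genes were lower at 48 h, with a median of -0.85. Arntl, Npas2 and Clock, which peak opposite to Dbp and the Per genes, had a median of -0.54 (-0.54, -0.69 and -0.09). This argues against a different time of day at collection as the whole cause. Pan-neuronal genes had a median of -0.22 (quartiles -0.38 to -0.07), which argues against a general loss of neurons alone. Other neuronal and brain region lists ran from -0.69 for striatum markers to 0.54 for hippocampus markers. Glutamate receptors lay at -0.59, cortex neuron markers at -0.45 and the GABA list at -0.36. The pan-neuronal test does not cover a loss of particular kinds of neurons, which stays open. The collection times are not given, and a response of the clock genes to the treatment stays open as a hypothesis.

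For each comparison of 2 times, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real grouping gave 98 genes at 1.5 h, 3737 at 12 h and 2209 at 48 h against control, and the highest other split 5, 0 and 0. Between times it gave 5873, 2757 and 3141 genes, and the highest other split 1, 2 and 2324. In each of these 6 comparisons 1 split, the real one, gave as many genes. The split with 2324 genes put 1.5 h replicates 1 and 3 with 48 h replicate 3, the libraries with negative length slopes, which points to a structure of the samples. For gene lists the real grouping gave 12, 18, 26, 17, 15 and 20 in the order 1.5 h, 12 h and 48 h against control, 12 h against 1.5 h, 48 h against 12 h and 48 h against 1.5 h. The highest other splits gave 19, 23, 30, 20, 24 and 31, and 5, 6, 4, 3, 9 and 5 of the 10 splits gave as many lists. The number of lists past the threshold therefore did not set the real grouping apart from other splits in any comparison. For the test across all 4 groups, 1 of 100 splits gave 6786 genes, the real one, and the highest other gave 999. A random grouping is therefore an unlikely source of that count. Splits cannot separate the treatment from anything else that the libraries of a group share.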

How the results depend on the processing

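The length correction, limma-voom on recovered reads and the fit without 1.5 h replicates 1 and 3 were chosen after the data were seen. Of 3497 alternative values of 269 named gene comparisons, 0 reversed, 3174 kept their side of the threshold, 236 were weaker and 87 stronger. Among the 3174, 60 values uncalled in both fits had the other sign. At 12 h, 2342 genes rose and 1395 fell, but 2175 and 2431 after quantile normalization, and the NF-kB median at 1.5 h went from 0.37 to -0.01 with length correction. Where no cause is given, the cause was not tested.

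Counts of changed genes are given in the order 1.5 h (98), 12 h (3737) and 48 h (2209) against control, 12 h against 1.5 h (5873), 48 h against 12 h (2757) and 48 h against 1.5 h (3141). A replicate block, with fewer libraries (11) and 4 residual degrees of freedom, gave 4, 1321, 724, 1134, 470 and 866, and 1534 for all 4 groups (6786). Also requiring a 2-fold change gave 63, 989, 730, 1581, 774 and 881. Fitting only the 2 groups gave 5, 7279, 3789 and 2384 in the first 4 and 559 in the last. Without 1.5 h replicates 1 and 3 the first 5 were 23, 6211, 4682, 2409 and 5405. At 1.5 h the count was 27 with no filter on low values and 49 with limma-voom. Of the calls with limma-voom at 1.5 h, 48 of 49 were the same genes, and with length correction 43 of 76.

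Leaving out 1 library gave 11 to 8071, 2293 to 2715, 1206 to 1788, 3408 to 9667, 1614 to 2651 and 1877 to 7812 genes. The counts of 8071, 9667 and 7812 were without 1.5 h replicate 2, whose composition differed from that of replicates 1 and 3. Without both 1.5 h replicates 1 and 3 a single 1.5 h library is left, which the fit assumes to vary like the other groups.

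There were 73 shared calls between times, 1.5 h and 12 h, 45 shared calls between times, 1.5 h and 48 h, and 1072 shared calls between times, 12 h and 48 h. These were 4, 2 and 291 with the block, 21, 11 and 2338 without 1.5 h replicates 1 and 3, 5, 3 and 2183 with only the 2 groups, and 43 and 28 for the first 2 with limma-voom. With length correction 29 were shared between 1.5 h and 48 h. Leaving out 1 library gave 11 to 1744, 7 to 1845 and 526 to 937.

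Lists past the threshold, in the same order, numbered 12, 18, 26, 17, 15 and 20. With an estimated correlation they were 0, 2, 0, 0, 0 and 0, and at 1.5 h 4 with fry and 7 with length correction. Leaving out 1 library gave 12 to 16, 17 to 19, 23 to 28, 12 to 17, 12 to 15 and 18 to 23.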

Other observations

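Tests of no hypothesis beyond those above were run, and every value in this part was chosen after the data were seen. Ttr, the abundant transcript of choroid plexus, was at 420, 659 and 494 FPKM in the controls, 5.54, 1.96 and 439 at 1.5 h, 708, 296 and 535 at 12 h and 978, 31.0 and 127 at 48 h. Hbb-bs, a globin gene of red blood cells, was at 212 FPKM in 1.5 h replicate 1 and at 0.221 to 28.1 in the other 11 libraries. Glo1, which varies in copy number between mouse strains, was at 54.4 to 65.7 FPKM in controls, 89.5, 32.9 and 94.0 at 1.5 h, 29.2 to 31.8 at 12 h and 61.3 to 89.9 at 48 h. Wdfy1, also on the list of strain-variable genes, was at 6.34 to 8.44 FPKM in controls, 5.7 to 6.97 at 1.5 h, 10.1 to 11.7 at 12 h and 8.41 to 9.52 at 48 h. That list did not pass at 12 h (camera adjusted p = 0.991). Whether the mice of the groups differ in stock was not tested. Nnt, which carries a deletion in some C57BL/6 strains, was at 0.00776 to 0.0756 FPKM in the 12 libraries. The Y chromosome genes Ddx3y, Uty, Kdm5d and Eif2s3y were listed at 0 in all 12 libraries, and Xist was at 8.43 to 34.5 FPKM.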
